A study of Mus musculus with 8 samples.

How the data were processed

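The data are raw 10x Chromium matrices of UMI counts, 1 per library, with 737280 barcodes and 31053 genes each, which the authors deposited before any filter on barcodes. The counts came from Cell Ranger 3.0.1 with the 10x reference 3.0.0 of GRCm38 (annotation version 93), per the submitters' processing notes, which also name the build mm10. Per the labels' protocols, liver cells of 3 mice per group were pooled, sorted as CD45 positive and CD31 negative on an Aria-II, loaded at 7000 cells per sample with about 60% recovery, and sequenced on a NextSeq 550 at about 60000 reads per cell. The submitters' processing notes give a Seurat 2.3.4 workflow that kept cells with 100 to 3000 genes and under 50% mitochondrial and ribosomal counts, and clustered 30 principal components of 1000 variable genes at resolution 0.45. Their cell names were not used here, so classes were rebuilt and a difference from the study may come from rebuilt names. The files hold 71 genes with a repeated symbol, which were kept apart by identifier.

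Cells were called as barcodes with at least 10% of the 99th percentile of the top 4200 barcodes (the loaded cells times the stated recovery), which set limits of 981.7 and 972.9 UMIs in WT, 1163.2 and 1136.5 in T2, 627.9 and 769.8 in RIP3, and 644.4 and 765.6 in IKK2. The called barcodes numbered 3817, 3799, 3808, 3535, 1705, 1774, 1806 and 1794 in WT, T2, RIP3 and IKK2 (replicates 1 and 2 of each in turn), and 3776, 3758, 3776, 3525, 1688, 1750, 1781 and 1776 passed the stated filter. The stated filter with no calling step would keep 4463, 4492, 4510, 4296, 2468, 1994, 1946 and 1974 barcodes. Scrublet scored doublets, and the highest scores were removed at 0.8% per 1000 cells, which took 1.36% to 3.03% of the cells of a library. Scrublet's automatic threshold took 0.05% to 2.02% and was replaced after this had been seen.

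Counts were normalised to 10000 per cell and logged, and 2000 variable genes without immunoglobulin and T cell receptor variable, mitochondrial, ribosomal, haemoglobin and sex-linked genes were scaled with a limit of 10. Clustering used genes seen in at least 10 cells, 30 principal components, 15 neighbours, shared neighbours at a Jaccard index of at least 0.0667, and Leiden at resolution 1 with seed 7. A cluster took a class name from markers fixed before the data were examined, which passed at 2-fold over the other cells (prior of 20 CPM) in at least 10% of its cells; it needed 3 markers and more of its own class than of another among its top 10 genes. Cluster 6 (as many NK or ILC1 as gamma-delta T cell genes) and cluster 22 (under 3 markers) stayed unnamed and are compared by number. The rule for scoring markers was written after the clusters had been seen, and clustering was run more than once while the list of ribosomal genes was corrected. B cells are clusters 0 and 17, T cells 1, 8 and 13, macrophages 2 and 4, NK or ILC1 cells 9 and 15, and cycling cells 16, 19 and 21, of which 16 is mostly T2.

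Counts were summed per library and class and tested with edgeR's quasi-likelihood test on all 8 libraries (TMM scaling, filterByExpr at a minimum count of 10, 4 residual degrees of freedom) in the 11 classes with at least 20 cells in every library, with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. Shares of 18 classes were tested with the same tool on cells per class. The main comparisons are T2 with WT, RIP3 with T2 and IKK2 with T2; RIP3 and IKK2 with WT and with each other are secondary. These tests, the gene lists, the named genes rule and the main alternatives were fixed before the data were examined. Errors beside log2 values, marked SE, are the absolute log2 value divided by the square root of the quasi-likelihood F statistic. They are thus approximate standard errors. Errors beside shares are SDs over 2 libraries. Where a group had 0 counts of a gene, the fold is given as at least the value at a floor of 3 counts over the group; with 1 to 3 counts, as a ratio with an exact 95% interval. Intervals and floors cover counting error only.

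Lists with at least 5 tested genes in a class were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists and classes of a comparison. The 205 tests per comparison are summarised as counts. The lists described one by one, a choice made after the results had been seen, are in Kupffer cells the NF-kB and TNF response, chemokines and receptors, immediate early and dissociation response, identity, lipid- and scar-associated, iron and haem, glycolysis and hypoxia, MHC class II and hepatocyte transcript lists; in classical monocytes type I interferon, MHC class II, lipid- and scar-associated, and complement and phagocytosis; in T cells cytotoxicity, checkpoint, naive, residency and regulatory T cell; in NK or ILC1 cells cytotoxicity; in cluster 6 cytotoxicity and cell cycle; and in pDCs MHC class II and class I. The lists of erythroid, endothelial, stellate or fibroblast, cholangiocyte and platelet transcripts had too few tested genes in every class. A list of sex-linked genes was called in 2 of 2 classes for T2 with WT (lowest camera adjusted p = 2e-13, but adjusted p = 0.058 with an estimated correlation) and is given with the sex of the pools in the closing section. In pDCs its median of -0.10 and mean of 3.75 differed in sign.

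The rule for named genes has 4 parts. In the 5 classes with most cells it takes up to 3 genes up and 3 down with the largest change among those with an adjusted p under 0.05, at least 16 counts per library on average in the higher group and no overlap between the libraries of both groups, leaving out immunoglobulin and T cell receptor segments, predicted, mitochondrial, ribosomal, sex-linked and contaminating genes. For each described list it takes up to 4 members with the smallest adjusted p. It also takes Ripk3, Traf2, Casp8, Ikbkb, Mlkl and Ripk1, and the class markers. Genes of that set that lost their call without 1 library, or whose counts matched free RNA, are mostly left out of the text. Free RNA was estimated from barcodes with up to 100 UMIs and scaled by transcripts of other lineages, taking the lower of 2 estimates; the limit on empty droplets was raised from a smaller one and the estimate changed after seeing the data.

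The libraries of a group were checked for shared barcodes: 26 pairs matched in WT, 20 in T2, 28 in RIP3 and 5 in IKK2, against 19.7, 18.3, 4.1 and 4.4 by chance, at most 1.64% of the smaller library, so they were treated as separate wells. The excess in RIP3 was not explained. The scripts were tested on simulated data with known changes. For T2 with WT 52.9% of 473 genes changed 2-fold were recovered, 89.7% of those with at least 50 UMIs, and 82.8% of 472 genes changed 4-fold. For RIP3 with T2 the shares were 41% of 470 and 74.8% of 481, and for IKK2 with T2 44% of 479 and 82.3% of 475. False calls made up 5.73%, 4.43% and 4.34% of the calls. All 5 raised lists were called in each, and 5, 2 and 4 with an estimated correlation. Of the other lists 4 of 72, 6 of 74 and 6 of 75 were called too. Genes were simulated independently of each other, with the same dispersion for all genes of a class. In the real data genes of a list can move together and differ in spread. The rates of recovered genes, false calls and called lists therefore need not hold there. For shares 80, 79 and 80 of 80 changed classes were recovered, and 38, 34 and 29 of 280 other classes were also called. The simulated shares were rescaled to a fixed total, so the shares of those other classes moved too. Their calls therefore do not measure a rate of false calls, and small differences in shares stay uncertain.

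Chosen after seeing the data were the shares with macrophages left out, the shares of broad lineages, Y-positive cells alone, Scrublet's automatic threshold, cluster 6 joined to NK or ILC1 cells, cycling or B cells left out, a minimum of 10 cells, the fits within T cell clusters, the set of macrophage transcripts in Kupffer cells, and the set of unchanged lists counted in the simulation. Coordinates are from GENCODE M21 (GRCm38), matched by gene identifier, which is a later annotation than the one used for counting. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.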

Results

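The data are single-cell RNA profiles of immune cells from mouse liver, sorted as CD45 positive and CD31 negative, in 4 groups of 2 libraries each. The groups are wild type (WT), mice whose hepatocytes lack Traf2 and caspase-8 (T2), the same mice with Ripk3 missing from every cell (RIP3), and the same mice with IKK-beta also missing from hepatocytes (IKK2). TRAF2 and caspase-8 act downstream of death receptors, RIPK3 is a kinase of the necroptosis pathway, and IKK-beta activates NF-kB. Cells of 3 mice per group were pooled before loading, so the libraries of a group are wells that may hold the same pool, and the p-values measure a spread that may be technical rather than a spread between mice. After filtering, 3662 and 3645 cells were kept in WT, 3666 and 3426 in T2, 1665 and 1726 in RIP3, and 1756 and 1751 in IKK2. The total counts per library were 11612365 and 11481940 UMIs in WT, 18393970 and 17997033 in T2, 4722223 and 5103784 in RIP3, and 4976198 and 5452171 in IKK2. The median UMIs per kept cell were 1920 and 1888 in WT, 3770.5 and 4040 in T2, 1474 and 1636.5 in RIP3, and 1610 and 1691 in IKK2, so cell number and depth differed by group. Sex differed too. Of the cells with Xist or Y-linked transcripts, 53.19% and 56.22% were Xist-positive in T2, 71.41% and 67.01% in RIP3, and 0% in WT and IKK2. Comparisons of T2 or RIP3 with WT or IKK2 therefore also differ in sex.

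Ripk3, the gene removed from every cell of the RIP3 group, was counted first as a check of the labels. It had 206 and 193 UMIs over all kept cells in WT, 226 and 200 in T2, 73 and 84 in IKK2, and 8 and 7 in RIP3. Against T2 the RIP3 level was 7.68-fold lower (log2 -2.94 ± 0.25, SE, n = 2 libraries per group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.05e-10). Traf2, Casp8 and Ikbkb were removed from hepatocytes only, which the CD45 sort leaves out, so their levels here do not check the deletion. In these immune cells Traf2 was lower in T2 than in WT (log2 -0.88 ± 0.11, edgeR adjusted p = 3.46e-07) and 2.05-fold and 2.14-fold higher in RIP3 and IKK2 than in T2. Ikbkb was higher in T2 than in WT by 0.31 ± 0.07 (edgeR adjusted p = 0.000749). Among genes of the same pathway, Mlkl, which encodes the effector of necroptosis, rose in T2 over WT by 0.63 ± 0.21 (log2), and Ripk1 by 0.29 ± 0.11, with adjusted p of 0.0122 and 0.0217 by the same test. Ripk3 itself was lower in T2 than in WT (log2 -0.40 ± 0.11, edgeR adjusted p = 0.00319). These are sums over all kept cells, whose makeup differed between the groups.

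The comparison of T2 with WT asks how the liver's immune cells change when hepatocytes lose Traf2 and caspase-8. In T2 a population of macrophages that was rare in WT became the most abundant of the named classes. Monocyte-derived macrophage-like cells, named from markers such as Spp1 and Mmp12 in cluster 2 and Cx3cr1 and Cd63 in cluster 4, made up 55.8% ± 1.52 (SD, n = 2) of the T2 cells and 0.958% ± 0.113 of the WT cells, a 58-fold higher share (log2 5.86 ± 0.08, SE). Classical monocyte-like cells rose from 1.79% to 8.86%, 4.94-fold, and neutrophil-like cells 10-fold, from 0.096%. B cell-like cells fell 20.1-fold, from 20.5% ± 0.783 to 1.02% ± 0.328, T cell-like cells 5.42-fold, from 25.1% ± 1.06 to 4.65% ± 1.1, and Kupffer cell-like cells, the resident macrophages of the liver, 4.26-fold, from 13.3% ± 0.0148 to 3.12% ± 0.0495. The class names rest on marker genes and are used without "like" from here on.

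Endothelial cells, which the CD31 sort depletes, were 8.36-fold lower, at 0.06% of the cells of each T2 library against 0.52% and 0.49% in WT. NK or ILC1 cells were 3.73-fold lower in T2, plasmacytoid dendritic cells (pDCs), the main producers of type I interferon, 2.73-fold lower, and cluster 6, which stayed unnamed because it carried markers of NK cells and of gamma-delta T cells, 3.46-fold lower. Conventional dendritic cells of type 2 (cDC2) were 1.76-fold higher, gamma-delta T cells 1.66-fold higher and cycling cells 2.68-fold higher. Of the cycling clusters, cluster 16 went from 0.246% and 0.165% to 3.25% and 2.92%, whereas cluster 19 lay at 0.245% and 0.175% in T2 against 0.41% and 0.549% in WT, and cluster 21 at 0.245% and 0.204% against 0.573% and 0.686%. All 18 classes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11 higher and 7 lower, with adjusted p = 3.91e-67 for the macrophages. Hepatocytes (log2 0.84) and cDC1 (0.25) did not pass without T2 replicate 2, and migratory dendritic cells did not without T2 replicate 1 (0.79) or WT replicate 2 (0.80). Without WT replicate 1 hepatocytes (0.61) and cDC1 (0.42) did not pass either, and hepatocytes did not without either RIP3 library (1.15) or with every barcode of 500 or more UMIs (0.47). Among Y-positive cells alone, a choice made after seeing the data, the gamma-delta T cell share lay at -0.30 (log2). An exact permutation test of 2 against 2 libraries cannot go below p = 0.333. The sort, the UMI limit for calling cells and the deeper T2 libraries can also set shares. With every barcode of 500 or more UMIs taken as a cell, B cells were 10.5-fold and T cells 3.62-fold lower in T2 than in WT, and macrophages 54.8-fold higher. At a clustering resolution of 2 the macrophage log2 ratio was 4.75, but clusters of 1187 and 769 cells closest to macrophages stayed unnamed there. That ratio leaves them out. Shares sum to 100, so a class can fall because another rose. With the macrophages left out of the total, an alternative chosen after seeing the data, B cells were 9-fold lower, T cells 2.42-fold, Kupffer cells 1.9-fold, NK or ILC1 cells 1.67-fold, cluster 6 1.54-fold and pDCs 1.22-fold lower. On that basis gamma-delta T cells were 3.73-fold, classical monocytes 11.1-fold, cDC2 3.95-fold, cycling cells 6-fold and neutrophils 22.2-fold higher, and endothelial cells 3.87-fold lower.

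The T2 macrophages were split between cluster 2, which held 31.7% and 30.3% of the T2 cells, and cluster 4, which held 25.2% and 24.5%. The few WT macrophages were almost all in cluster 4, at 1.01% and 0.85% of the cells. Because genes that define these clusters differ between groups, the shares of whole lineages were also compared. Monocytes and macrophages together, Kupffer cells included, made up 69.1% and 66.6% of the T2 cells and 16.4% and 15.7% of the WT cells, a 4.23-fold higher share (log2 2.08 ± 0.04; edgeR quasi-likelihood adjusted p = 1.07e-08).

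**Figure D1:**
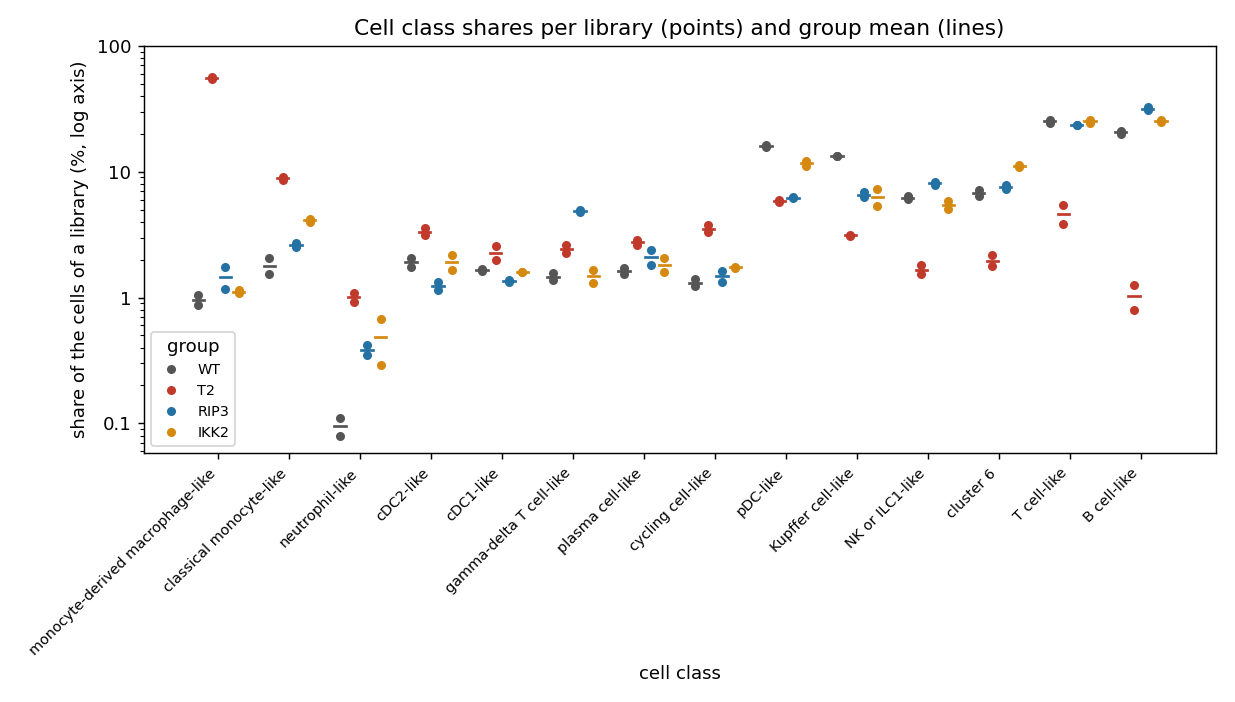
Share of the cells of each library (%, log axis) in 14 cell classes, with 1 point per library, a line at each group's mean and a colour per group. Macrophages lie at 55.8% on average in T2 and at 1.45% or less in the other groups, while B cells lie at 1.02% in T2 and between 20.5% and 31.7% elsewhere.

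Kupffer cells of T2 carried an inflammatory programme. Here and below, gene values given with "by" or "at" are log2 fold changes of summed counts. Their SE is derived from the F statistic, with 2 libraries per group. Cxcl2, a chemokine that attracts neutrophils, was 130-fold higher than in WT (log2 7.03 ± 0.19, SE, n = 2; edgeR quasi-likelihood adjusted p = 1.98e-63), and Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, rose by 1.67 ± 0.09. Of the 26 measured genes of the NF-kB and TNF response list, 14 rose and 0 fell, 15 and 0 adjusted over the list alone (camera adjusted p = 5.37e-24, and adjusted p = 0.0339 with an estimated correlation). Ccl3 was up by 2.76 ± 0.20 and Bcl2a1b by 1.93 ± 0.12. Of the 19 chemokines and chemokine receptors, 12 rose and 1 fell, 13 and 2 adjusted over the list alone, among them Cx3cr1, the fractalkine receptor, at 24.9-fold, and Ccl9 at 10.6-fold (camera adjusted p = 5.37e-24, and adjusted p = 0.0339 with an estimated correlation). The immediate early and dissociation response list, transcription factors and phosphatases that cells switch on within minutes of a stimulus or of tissue digestion, had 19 of 29 genes up and 2 down, 20 and 2 adjusted over the list alone. Dusp1 rose by 3.47 ± 0.12, Zfp36 by 2.94 ± 0.14 and Junb by 2.36 ± 0.11 (camera adjusted p = 1.01e-37, but adjusted p = 0.0596 with an estimated correlation).

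Genes that mark the resident Kupffer cell fell at the same time. Of the 22 measured genes of the Kupffer cell identity list, 16 fell and 4 rose, 16 and 5 adjusted over the list alone (camera adjusted p = 7.67e-07, but adjusted p = 0.0596 with an estimated correlation). Cd163, the receptor that clears haemoglobin, was 6.92-fold lower (log2 -2.79 ± 0.19) and Slc40a1, the iron exporter ferroportin, changed by -0.79 ± 0.06, whereas Marco, a scavenger receptor, and Id3, a factor that Kupffer cells need, each rose by 1.12. At a clustering resolution of 2, Marco led a Kupffer cell cluster of 353 cells and Id3 another of 111 cells. Values of Marco and Id3, here and below, can therefore also reflect the mix of such cells. The iron and haem list had 7 of 11 genes down and 1 up, the same adjusted over the list alone (camera adjusted p = 1.71e-08, but adjusted p = 0.0596 with an estimated correlation). Spic, the factor behind iron-recycling macrophages, was at -1.46 ± 0.22. In the lipid- and scar-associated macrophage list 7 of 15 genes rose and 1 fell, 8 and 3 adjusted over the list alone (camera adjusted p = 2.54e-07, but adjusted p = 0.0596 with an estimated correlation). Trem2, a lipid receptor, was up by 2.34 ± 0.14, Cd9 by 3.14 ± 0.22 and Plin2, a coat protein of lipid droplets, by 1.38 ± 0.12. Of 12 glycolysis and hypoxia genes 8 rose and 1 fell, the same adjusted over the list alone, including Gapdh by 1.04 ± 0.08 and Eno1 by 1.09 ± 0.11 (camera adjusted p = 2.82e-05, but adjusted p = 0.0771 with an estimated correlation). Of 8 MHC class II genes, which present antigen, 6 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 3.05e-05, but adjusted p = 0.144 with an estimated correlation). H2-Eb1 was up by 0.59 ± 0.06 and Cd74 by 0.46 ± 0.05.

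Some transcripts of other cells moved with these groups. For 12 genes abundant in the T2 macrophages and outside the lists, a set chosen after seeing the data, the rise in T2 Kupffer cells reached a median of 4.12% of the macrophage level (range 2.8% to 40.9%), against 52.3% for Cxcl2, 55.2% for Cx3cr1 and 66.9% for Trem2. Other named genes lay inside that range: Cd9 at 18.1%, Ccl9 at 25.2%, Atf3 at 33.5% and Junb at 37.4%. The upper end of the range is Ccrl2 alone, and the next highest gene of the set, Anxa1, stood at 6.32%. Hepatocyte transcripts in the Kupffer cells fell, 8 of 11 with 1 up and the same adjusted over the list alone, with Alb 6.16-fold lower and Fabp1, at 0 counts in T2, at least 13.2-fold lower (floor of 3 counts over the group; camera adjusted p = 2.8e-05, but adjusted p = 0.102 with an estimated correlation). Among the genes with the largest changes in Kupffer cells, Htra3, a secreted protease with 0 counts in WT, was at least 51.6-fold higher and Cd209g, a lectin with 0 counts in T2, at least 9.84-fold lower.

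**Figure D2:**
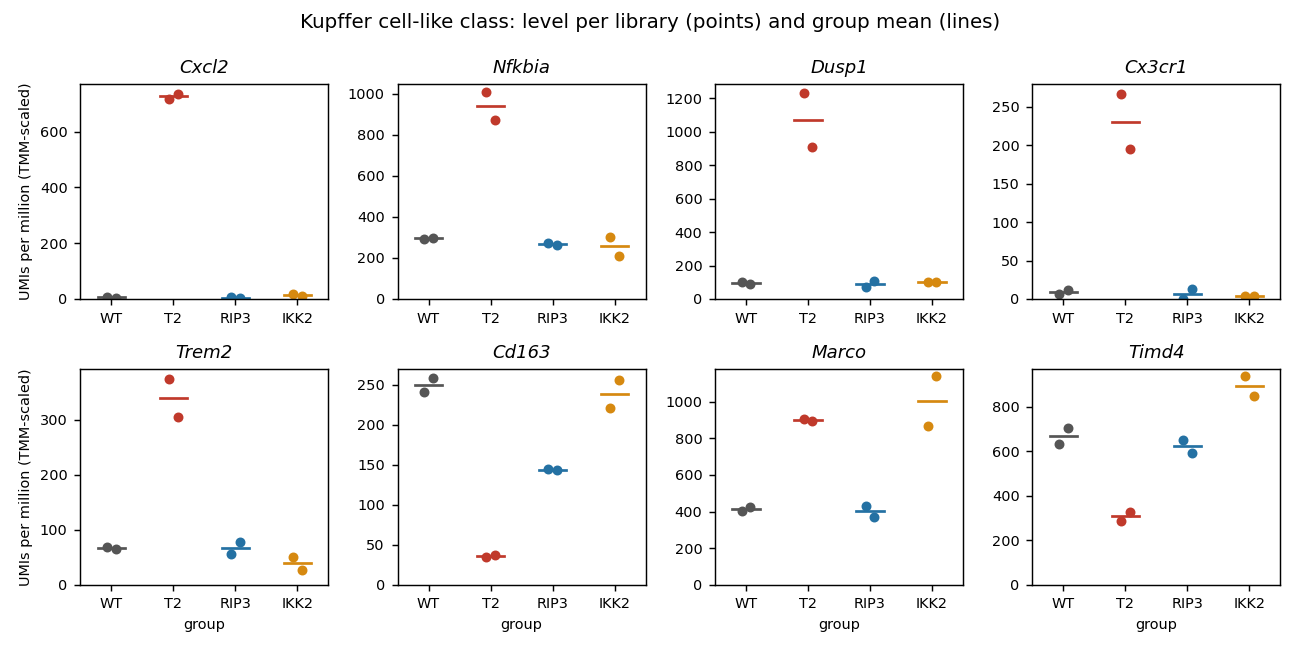
CPM (UMIs, TMM-scaled) of 8 genes in the Kupffer cells of each library, with 1 point per library, a line at each group's mean and groups along the horizontal axis. Cxcl2, Nfkbia, Dusp1, Cx3cr1 and Trem2 lie highest in T2, and Cd163 lies lowest there.

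In summed counts, classical monocytes of T2 had higher macrophage genes and lower interferon genes than those of WT. Trem2 rose by 2.22 ± 0.26 and Apoe, which carries lipid, by 2.69 ± 0.14; in their lipid- and scar-associated list 7 of 15 genes rose and 2 fell, 8 and 4 adjusted over the list alone (camera adjusted p = 8.27e-05, but adjusted p = 0.0771 with an estimated correlation). In the complement and phagocytosis list 9 of 15 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.21e-06, but adjusted p = 0.0771 with an estimated correlation). Axl, a receptor for dying cells, was 6.68-fold higher and C3ar1, the C3a receptor with 0 counts in WT, at least 15.8-fold higher. Of 7 MHC class II genes 4 rose and 0 fell, 7 and 0 adjusted over the list alone, including H2-DMa by 1.31 ± 0.14 and the protease Ctss by 0.96 ± 0.08 (camera adjusted p = 4.1e-09, but adjusted p = 0.102 with an estimated correlation). Of 23 type I interferon response genes 0 rose and 13 fell, 0 and 16 adjusted over the list alone, among them Ifi27l2a at -0.70 ± 0.08, Ifi204 at -0.99 ± 0.18 and Ifi47 at -1.76 ± 0.30 (camera adjusted p = 1.2e-08, but adjusted p = 0.102 with an estimated correlation). At a clustering resolution of 2, a cluster of 584 cells closest to classical monocytes was led by Chil3 and Thbs1. Another, of 505 cells, was led by Hp and Ifitm6. Gene values of classical monocytes, here and in the comparisons below, can therefore also reflect the mix of such cells.

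T cells of T2 held different clusters from those of WT. Cluster 1 made up 74.9% and 76.6% of the WT T cells but 19.7% and 21% of the T2 T cells, cluster 8 went from 20.3% and 19.3% to 50.7% and 41.9%, and cluster 13, marked by Gzmk, Cd8a and Klrg1, from 4.86% and 4.17% to 29.6% and 37.1%. Over the whole class, 8 of 12 tissue residency genes rose and 2 fell, 9 and 2 adjusted over the list alone (camera adjusted p = 2.42e-08, but adjusted p = 0.0596 with an estimated correlation). Itgae, the integrin that holds T cells in epithelium, was 14.3-fold higher and Rgs1, a brake on chemokine signals, up by 1.34 ± 0.10, while Cxcr6 fell by 0.75. In the checkpoint and exhaustion list 5 of 13 rose and 2 fell, 7 and 2 adjusted over the list alone, led by Pdcd1, which encodes PD-1, at 10.2-fold (log2 3.35 ± 0.43; camera adjusted p = 0.000397, but adjusted p = 0.0869 with an estimated correlation). In the regulatory T cell list 4 of 10 rose and 2 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.00116, but adjusted p = 0.0826 with an estimated correlation). Tnfrsf4, which encodes OX40, was 17-fold higher and Ctla4 up by 1.97 ± 0.32. In the naive and central memory list 5 of 14 genes fell and 1 rose, 7 and 1 adjusted over the list alone (camera adjusted p = 8.08e-06, but adjusted p = 0.0813 with an estimated correlation). Satb1, an organiser of chromatin in T cells, was at -1.87 ± 0.20. The cytotoxicity and effector list went both ways and was not called (camera adjusted p = 0.651): 4 of 23 rose and 5 fell, the same adjusted over the list alone, with the granzyme Gzmk up by 3.14 ± 0.33 and the NK receptors Klrc1 and Klrk1 down, at -1.88 ± 0.20 and -1.65 ± 0.19.

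**Figure D3:**
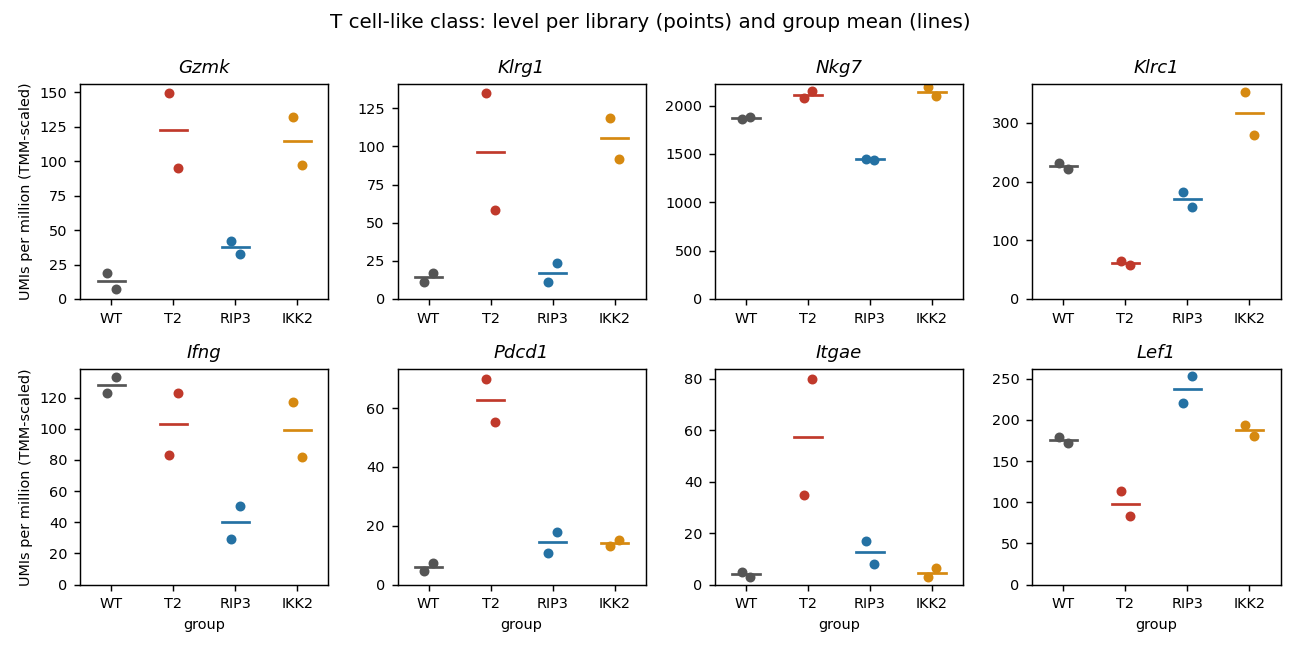
CPM (UMIs, TMM-scaled) of 8 genes in the T cells of each library, with 1 point per library, a line at each group's mean and groups along the horizontal axis. Pdcd1 and Itgae lie highest in T2, Gzmk lies high in T2 and IKK2, and Ifng lies lowest in RIP3.

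Cytotoxic genes fell in NK or ILC1 cells and in cluster 6 of T2. NK or ILC1 cells of WT held 138 and 139 cells of cluster 9 and 83 and 95 of cluster 15, which is rich in Gzma and Prf1, against 40 and 40 and 16 and 22 in T2. In this class 8 of 20 cytotoxicity genes fell and 0 rose, 10 and 0 adjusted over the list alone (camera adjusted p = 1.62e-09, but adjusted p = 0.0771 with an estimated correlation). Prf1, the pore-forming protein perforin, was at -1.85 ± 0.28 and Klrc1 at -1.29 ± 0.20. In cluster 6, 10 of 17 fell and 0 rose, 13 and 0 adjusted over the list alone (camera adjusted p = 3.55e-12, and adjusted p = 0.0421 with an estimated correlation). Klrc1 was at -2.56 ± 0.20 and the chemokine Ccl5 at -0.62 ± 0.05. Cluster 6 also gained cell cycle transcripts: 9 of 12 rose and 0 fell, 12 and 0 adjusted over the list alone (camera adjusted p = 2.71e-12, and adjusted p = 0.0421 with an estimated correlation). Stmn1, a regulator of microtubules in dividing cells, was 34-fold higher and Rrm2, which makes DNA precursors and had 0 counts in WT, at least 18.2-fold higher.

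In pDCs both antigen presentation lists fell. Of 11 MHC class II genes 8 fell and 0 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 4.47e-13, but adjusted p = 0.0771 with an estimated correlation). H2-Eb1 was at -0.62 ± 0.07 and H2-Aa at -0.68 ± 0.06. Of 16 MHC class I genes 10 fell and 0 rose, 11 and 0 adjusted over the list alone (camera adjusted p = 1.31e-07, but adjusted p = 0.0771 with an estimated correlation). H2-D1 was at -0.38 ± 0.05 and H2-Q7 at -0.82 ± 0.12. Il1b, which monocytes make, was 16.5-fold higher in the pDCs, but 70.6% of its counts there matched free RNA in the droplets. The same held for Lyz2, a myeloid gene that was 3.9-fold higher in B cells, with 100% of its counts matching free RNA.

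Over the 11 classes with enough cells, 2857 genes rose and 2038 fell in T2, 4895 calls in all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cycling cells gave 753 of the rises and 487 of the falls, and their cells lie mostly in cluster 16 in T2 but in clusters 19 and 21 in WT. Without that class, a choice made after seeing the data, 3655 calls remained. Leaving out T2 replicate 2 left 3042 calls. Of the 205 tests of lists within classes 113 were called, 74 higher and 39 lower, of which 7 held with an estimated correlation.

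The comparison of RIP3 with T2 asks what the loss of Ripk3 changes in mice whose hepatocytes lack Traf2 and caspase-8. The macrophage population of T2 was nearly missing: it made up 1.45% ± 0.412 (SD, n = 2) of the RIP3 cells, a 38.5-fold lower share (log2 -5.27 ± 0.10, SE). B cells reached 31.7% ± 1.4, 31.1-fold higher than in T2, and T cells 23.5% ± 0.194, 5.08-fold higher. NK or ILC1 cells were 4.86-fold higher, Kupffer cells 2.11-fold higher and gamma-delta T cells, which are quick producers of IL-17, 2-fold higher, while classical monocytes were 3.37-fold lower, cDC2 2.7-fold lower and cycling cells 2.39-fold lower. The pDC share was not called (log2 0.09 ± 0.12). Of 18 classes 15 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 higher and 8 lower, with adjusted p = 7.74e-58 for the macrophages. Migratory dendritic cells did not pass without RIP3 replicate 1 (log2 -1.04), nor cDC1 with every barcode of 500 or more UMIs (-0.35). With every barcode of 500 or more UMIs taken as a cell, B cells were 13.9-fold higher and T cells 3.5-fold higher than in T2. At a clustering resolution of 2 the log2 ratio of macrophages was -4.40 and that of classical monocytes 0.12. At that resolution clusters of 1187 and 769 cells closest to macrophages stayed unnamed, as did another of 584 cells closest to classical monocytes. Those ratios therefore cover only part of each class. Among Y-positive cells the log2 ratio of cycling cells was 0.05. With macrophages left out of the total, the Kupffer cell and gamma-delta T cell shares were no longer called and lay at -0.08 and -0.15 (log2). On that basis B cells were 14-fold, T cells 2.27-fold and NK or ILC1 cells 2.18-fold higher, and classical monocytes 7.53-fold, cDC2 6.03-fold, cycling cells 5.32-fold and pDCs 2.1-fold lower. Monocytes and macrophages as 1 lineage, Kupffer cells included, were 6.37-fold lower, at 11.2% and 10.1% of the RIP3 cells.

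In Kupffer cells many inflammatory genes were lower in RIP3 than in T2. Nfkbia changed by -1.81 ± 0.12 and Ccl3 by -2.70 ± 0.30, and Cxcl2, with 3 UMIs in RIP3, stood at a ratio of 149 (95% counting interval 50.7 to 722) in favour of T2. In the NF-kB and TNF response list 13 of 26 genes fell and 0 rose, 14 and 1 adjusted over the list alone (camera adjusted p = 5.62e-13, and adjusted p = 0.042 with an estimated correlation). In the immediate early list 18 of 29 fell and 0 rose, 21 and 0 adjusted over the list alone (camera adjusted p = 5.13e-37, and adjusted p = 0.042 with an estimated correlation). Dusp1 was at -3.57 ± 0.17. Against WT the same list was lower in RIP3 in all 11 tested classes by camera, though not with an estimated correlation, so low values were not particular to Kupffer cells. Of the chemokines and their receptors 9 of 19 fell and 1 rose, 13 and 1 adjusted over the list alone (camera adjusted p = 2.8e-15, and adjusted p = 0.042 with an estimated correlation). Cx3cr1 was at -5.10 ± 0.40 and Ccl9 at -2.53. In the lipid- and scar-associated list 8 of 15 fell and 0 rose, 9 and 0 adjusted over the list alone (camera adjusted p = 2.33e-11, and adjusted p = 0.042 with an estimated correlation). Trem2 was at -2.34 ± 0.21 and Plin2 at -2.18. Macrophage transcripts in T2 Kupffer cells, at a median of 4.12% of the macrophage level, stand on the T2 side of these values. Of 12 glycolysis and hypoxia genes 7 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.000348, but adjusted p = 0.0836 with an estimated correlation).

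Resident markers were higher in the RIP3 Kupffer cells. Of 22 identity genes 13 rose and 4 fell, 14 and 5 adjusted over the list alone (camera adjusted p = 5.19e-06, but adjusted p = 0.0602 with an estimated correlation). Timd4, a receptor for dying cells on embryo-derived Kupffer cells, was up by 1.02 ± 0.12 and Marco at -1.17 ± 0.11. In the iron and haem list 3 of 11 rose and 1 fell, 5 and 2 adjusted over the list alone, with Cd163 up by 1.99 ± 0.26 (camera adjusted p = 0.0149, but adjusted p = 0.142 with an estimated correlation); the call was lost without T2 replicate 1 (p = 0.0645) and without RIP3 replicate 2 (p = 0.0514). The MHC class II list was not called (0 up and 1 down of 8, camera adjusted p = 0.205). Hepatocyte transcripts were higher, 6 of 11 up and 1 down, 7 and 1 adjusted over the list alone (camera adjusted p = 0.00124, but adjusted p = 0.182 with an estimated correlation). Alb was up by 2.32. Gdpd3, a lysophospholipase D gene, was 13.4-fold higher in these cells, and Adamdec1, a protease of gut and inflammatory macrophages with 0 counts in RIP3, at least 19.7-fold lower.

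Some macrophage genes were lower in the monocytes of RIP3 than in those of T2. Trem2 changed by -3.37 ± 0.37 and Axl by -2.82 ± 0.30. In the complement and phagocytosis list 8 of 15 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 4.59e-05, but adjusted p = 0.0836 with an estimated correlation), and in MHC class II 3 of 7 fell and 0 rose, 7 and 0 adjusted over the list alone (camera adjusted p = 2.17e-09, but adjusted p = 0.107 with an estimated correlation). H2-DMb1 was at -1.84 ± 0.20. In the lipid- and scar-associated list 6 of 15 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 6.24e-05, but adjusted p = 0.096 with an estimated correlation, and p = 0.122 without RIP3 replicate 2). The interferon list was not called (camera adjusted p = 0.416), with 2 of 23 genes up and 0 down.

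In T cells, of which cluster 1 held 59.1% and 61% in RIP3, residency genes fell and naive genes rose. Of 12 residency genes 6 fell and 0 rose, 7 and 1 adjusted over the list alone (camera adjusted p = 3.41e-11, and adjusted p = 0.042 with an estimated correlation). Rgs1 was at -1.78 ± 0.11. Of 14 naive and central memory genes 6 rose and 0 fell, 11 and 1 adjusted over the list alone (camera adjusted p = 3.1e-09, but adjusted p = 0.0611 with an estimated correlation). Satb1 was up by 1.75 ± 0.21 and Lef1, a transcription factor of naive T cells, by 1.31 ± 0.19. In the checkpoint list 4 of 13 fell and 0 rose, 5 and 2 adjusted over the list alone (camera adjusted p = 6.93e-05, but adjusted p = 0.0796 with an estimated correlation). Ctla4 was at -2.56 ± 0.40 and Pdcd1 at -2.07 ± 0.42. The cytotoxicity list had 4 of 23 up and 7 down, 4 and 8 adjusted over the list alone (camera adjusted p = 0.00264, but adjusted p = 0.21 with an estimated correlation, and p = 0.0696 without RIP3 replicate 1). Klrg1 was at -2.37 ± 0.40 and Klrc1 at 1.46 ± 0.22. The regulatory T cell list was not called (2 up and 3 down of 10, camera adjusted p = 0.0705).

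Cytotoxic genes rose in cluster 6 and in NK or ILC1 cells of RIP3. In cluster 6, 8 of 17 rose and 0 fell, the same adjusted over the list alone, with Ccl5 up by 0.91 ± 0.05 and Klrc1 by 1.89 ± 0.23 (camera adjusted p = 1.08e-08, and adjusted p = 0.042 with an estimated correlation), while 8 of 12 cell cycle genes fell and 0 rose, 10 and 0 adjusted over the list alone (camera adjusted p = 3.1e-09, and adjusted p = 0.042 with an estimated correlation). Stmn1 was at -3.94 ± 0.44. In NK or ILC1 cells, with 107 and 108 cells of cluster 9 and 32 and 28 of cluster 15 in RIP3, 5 of 20 cytotoxicity genes rose and 0 fell, 8 and 0 adjusted over the list alone (camera adjusted p = 1.11e-05, but adjusted p = 0.129 with an estimated correlation). Klrc1 was up by 1.45 ± 0.21. In pDCs 9 of 16 MHC class I genes rose and 0 fell, 12 and 0 adjusted over the list alone, with H2-K1 up by 0.69 ± 0.07 and H2-Q7 by 1.27 ± 0.14 (camera adjusted p = 3.87e-16, and adjusted p = 0.042 with an estimated correlation), and 4 of 11 MHC class II genes rose and 1 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 1.57e-05, but adjusted p = 0.157 with an estimated correlation). In B cells Myc, a driver of cell growth, changed by -1.99 ± 0.28. Over the 11 classes 1759 genes rose and 2371 fell, 4130 calls in all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2724 without RIP3 replicate 2. Cycling cells, which lie in different clusters in T2 and RIP3, gave 311 of the rises and 533 of the falls, and 3286 calls remained without them. Of the 205 list tests 101 were called, 24 higher and 77 lower, of which 14 held with an estimated correlation.

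The comparison of IKK2 with T2 asks what the added loss of IKK-beta in hepatocytes changes. The T2 pool held Xist-positive cells and the IKK2 pool did not, so sex goes with this comparison. Here too the macrophages were rare, at 1.11% ± 0.0424 (SD, n = 2) of the cells, a 50-fold lower share than in T2. B cells made up 25.3% ± 0.414, 24.8-fold higher, T cells 25.2% ± 1.02, 5.45-fold higher, and cluster 6 11.04%, 5.62-fold higher. Kupffer cells were 2.02-fold higher and pDCs 2-fold higher, while classical monocytes were 2.16-fold lower, at 4.11%. Of 18 classes 17 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 higher and 10 lower, with adjusted p = 1.1e-58 for the macrophages. Endothelial cells did not pass without any 1 of the 4 libraries of these groups (adjusted p by the same test from 0.0686 to 0.175). Calls were also lost without IKK2 replicate 1 for cDC1, gamma-delta T cells, migratory dendritic cells and plasma cells, without IKK2 replicate 2 for cDC1 and neutrophils, without T2 replicate 1 for migratory dendritic cells and without T2 replicate 2 for cDC1. With every barcode of 500 or more UMIs cDC1 (log2 -0.39) and endothelial cells (1.59) did not pass. With every barcode of 500 or more UMIs taken as a cell, B cells were 11.1-fold higher and T cells 3.78-fold higher. At a clustering resolution of 2 the log2 ratio of macrophages was -4.83. That of classical monocytes was 0.67, called in the other direction (edgeR quasi-likelihood adjusted p = 0.000217). At that resolution clusters of 1187 and 769 cells closest to macrophages stayed unnamed, as did another of 584 cells closest to classical monocytes. Those ratios therefore cover only part of each class. Among Y-positive cells cDC1 (0.16), gamma-delta T cells (0.42) and plasma cells (0.45) lay above 0 (log2) and were not called. With macrophages left out of the total, Kupffer cells lay at -0.15 and pDCs at -0.16 (log2) and were no longer called. On that basis B cells were 11.1-fold, T cells 2.43-fold and cluster 6 2.51-fold higher, and classical monocytes 4.83-fold lower. Monocytes and macrophages as 1 lineage, Kupffer cells included, were 5.89-fold lower, at 12.3% and 10.7%.

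Kupffer cells of IKK2 had low inflammatory genes and high resident ones. Cxcl2 was 53.4-fold lower than in T2, Ccl3 changed by -3.46 ± 0.37 and Cd163 by 2.71 ± 0.24. In the NF-kB and TNF response list 12 of 26 genes fell and 0 rose, 13 and 0 adjusted over the list alone (camera adjusted p = 9.86e-14, and adjusted p = 0.049 with an estimated correlation). In the immediate early list 19 of 29 fell and 0 rose, 20 and 0 adjusted over the list alone (camera adjusted p = 8.11e-35, but adjusted p = 0.0554 with an estimated correlation). Dusp1 was at -3.36. Against WT the same list was lower in IKK2 in all 11 tested classes by camera, though not with an estimated correlation, so low values were not particular to Kupffer cells. Of the chemokines and their receptors 9 of 19 fell and 0 rose, 11 and 1 adjusted over the list alone (camera adjusted p = 9.86e-14, and adjusted p = 0.0431 with an estimated correlation). In the identity list 13 of 22 rose and 2 fell, 14 and 4 adjusted over the list alone (camera adjusted p = 1.51e-11, and adjusted p = 0.0409 with an estimated correlation). Timd4 was up by 1.54 ± 0.11. Of 11 iron and haem genes 7 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 6.34e-08, but adjusted p = 0.0509 with an estimated correlation). Hmox1, which breaks down haem, was up by 1.05 ± 0.14. In the lipid- and scar-associated list 8 of 15 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 2.12e-07, but adjusted p = 0.0509 with an estimated correlation). Trem2 was at -3.07 ± 0.25. Glycolysis genes fell, 4 of 12 with 0 up, 6 and 0 adjusted over the list alone (camera adjusted p = 0.0005, but adjusted p = 0.0837 with an estimated correlation), and MHC class II was not called (0 up and 1 down of 8, camera adjusted p = 0.785; median 0.02, mean -0.04). Hepatocyte transcripts were higher, 10 of 11 up and 1 down and the same adjusted over the list alone (camera adjusted p = 9.86e-14, but adjusted p = 0.0509 with an estimated correlation). Alb was up by 3.75 ± 0.27.

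MHC class II and complement genes were lower in the monocytes of IKK2 than in those of T2. All 7 MHC class II genes fell, also adjusted over the list alone, with H2-DMa at -1.58 ± 0.13 (camera adjusted p = 5.36e-10, but adjusted p = 0.11 with an estimated correlation), and 8 of 15 complement and phagocytosis genes fell and 1 rose, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00155, but adjusted p = 0.187 with an estimated correlation). Axl was at -3.51 ± 0.27. The lipid- and scar-associated list went both ways, 3 up and 4 down of 15, 4 and 6 adjusted over the list alone, with Trem2 at -1.39 ± 0.21 and the protease Ctsb at 0.98 ± 0.10; it was not called (camera adjusted p = 0.84), and its median of 0.09 and mean of 0.18 differed in sign from the test. The interferon list was not called either (2 up and 1 down of 23, camera adjusted p = 0.664; median 0.01, mean -0.07).

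In T cells, of which cluster 1 held 52.3% and 57.3% and cluster 13 21.4% and 17.4% in IKK2, NK receptors rose: Klrc1 by 2.35 ± 0.20 and Klrd1 by 1.19 ± 0.12. In the cytotoxicity list 6 of 23 rose and 1 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 2.29e-07, but adjusted p = 0.104 with an estimated correlation). Of 12 residency genes 8 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 1.42e-12, and adjusted p = 0.0409 with an estimated correlation). Rgs1 was at -1.78 ± 0.11. In the checkpoint list 4 of 13 fell and 2 rose, 5 and 2 adjusted over the list alone (camera adjusted p = 0.00371, but adjusted p = 0.111 with an estimated correlation). Pdcd1 was at -2.11 ± 0.42. Of 14 naive and central memory genes 7 rose and 1 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 1.55e-07, but adjusted p = 0.0686 with an estimated correlation). Satb1 was up by 1.35 ± 0.22. The regulatory T cell list was not called (1 up and 2 down of 10, camera adjusted p = 0.0759).

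Cytotoxic genes rose in cluster 6 and in NK or ILC1 cells of IKK2. In cluster 6, 9 of 17 rose and 0 fell, 12 and 0 adjusted over the list alone, with Klrc1 up by 2.53 ± 0.21 (camera adjusted p = 2.9e-14, and adjusted p = 0.0409 with an estimated correlation), and 9 of 12 cell cycle genes fell and 0 rose, 12 and 0 adjusted over the list alone (camera adjusted p = 2.68e-10, and adjusted p = 0.0431 with an estimated correlation). Stmn1 was at -4.13 ± 0.41. The NK or ILC1 class of IKK2 held 47 and 44 cells of cluster 9 and 55 and 44 of cluster 15, against 40 and 40 and 16 and 22 in T2. Within it 10 of 20 rose and 1 fell, 11 and 1 adjusted over the list alone (camera adjusted p = 1.27e-09, but adjusted p = 0.0806 with an estimated correlation). Prf1 was up by 1.97 ± 0.30. In pDCs 6 of 11 MHC class II genes rose and 0 fell, 8 and 0 adjusted over the list alone, with H2-Eb1 up by 0.68 ± 0.07 (camera adjusted p = 3.33e-10, but adjusted p = 0.0875 with an estimated correlation), and 7 of 16 MHC class I genes rose and 0 fell, 9 and 0 adjusted over the list alone (camera adjusted p = 6.87e-07, but adjusted p = 0.0729 with an estimated correlation). Nr4a1, an early gene of cell activation, was 18.7-fold lower in the pDCs of IKK2. Over the 11 classes 1815 genes rose and 2576 fell, 4391 calls in all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2905 without T2 replicate 2. Cycling cells, which lie in different clusters in T2 and IKK2, gave 345 of the rises and 591 of the falls, and 3455 calls remained without them. Of the 205 list tests 101 were called, 29 higher and 72 lower, of which 11 held with an estimated correlation.

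The groups that lack a further gene were then set against WT, to ask what still differed. Kupffer cells stayed scarce: their share was 2.02-fold lower in RIP3 and 2.11-fold lower in IKK2 than in WT, with edgeR quasi-likelihood adjusted p of 2.85e-15 and 6.03e-16. Gamma-delta T cells were 3.34-fold higher in RIP3 (4.90% against 1.47%), and pDCs 2.58-fold lower. Classical monocytes were 2.29-fold higher in IKK2, and cluster 6 was higher by 0.70 ± 0.10 (log2). The macrophage share was not called by edgeR's quasi-likelihood test in RIP3 (log2 0.59 ± 0.26, adjusted p = 0.0536) or in IKK2 (log2 0.21, adjusted p = 0.698). Without RIP3 replicate 2 it was called in RIP3 (log2 0.86, edgeR adjusted p = 0.048). Of 18 classes 9 were called in RIP3, 5 higher and 4 lower (5 calls without RIP3 replicate 1), and 7 in IKK2, 4 higher and 3 lower. Without 1 library calls were lost in RIP3 for NK or ILC1 cells, cDC2, classical monocytes, cluster 22 and neutrophils, and in IKK2 for endothelial cells and neutrophils.

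Genes still differed from WT in both groups. IKK2 T cells were richer in cytotoxic transcripts than WT T cells: 11 of 23 rose and 0 fell, 14 and 2 adjusted over the list alone, with Gzmk 8.5-fold, Klrg1 7.34-fold and the transcription factor Zeb2 (log2 2.37 ± 0.31) higher (camera adjusted p = 1.72e-20, but adjusted p = 0.0857 with an estimated correlation). Cluster 13, the Gzmk and Klrg1 cells, made up 21.4% and 17.4% of the T cells in IKK2 against 4.86% and 4.17% in WT. RIP3 T cells, of which it made up 8.48% and 8.09%, were poorer in them, 7 down and 2 up and the same adjusted over the list alone (camera adjusted p = 0.00063, but adjusted p = 0.314 with an estimated correlation). Ifng, the interferon of T and NK cells, was 3.13-fold lower and Gzmb at -0.91 ± 0.15. Kupffer cells of both groups had higher MHC class II genes, 4 up of 8 with 0 down, 6 and 2 adjusted over the list alone in RIP3 and 4 and 0 in IKK2, with Cd74 up by 0.42 ± 0.05 and 0.56 ± 0.05. The camera adjusted p was 4.2e-06 in RIP3, but adjusted p = 0.294 with an estimated correlation, and 4.18e-15 in IKK2, but adjusted p = 0.173 with an estimated correlation. Hepatocyte transcripts were also higher in the IKK2 Kupffer cells, 4 of 11 up and 0 down and the same adjusted over the list alone (camera adjusted p = 2.79e-08, but adjusted p = 0.173 with an estimated correlation), and were not called in RIP3 (camera adjusted p = 0.227). Their NF-kB and TNF response list was not called in RIP3 (camera adjusted p = 0.305) or IKK2 (camera adjusted p = 0.734). In RIP3 Kupffer cells 5 of 11 iron and haem genes fell and 0 rose, 6 and 0 adjusted over the list alone (camera adjusted p = 2.29e-06, but adjusted p = 0.13 with an estimated correlation). Fth1, the ferritin heavy chain, was at -0.47 ± 0.05. Interferon genes of classical monocytes were lower in both, 3 and 4 of 23 down with 0 up, 3 and 10 adjusted over the list alone, with Ifi204 at -1.39 ± 0.27 in RIP3 and Oasl2 at -3.45 ± 0.53 in IKK2. The camera adjusted p was 3.92e-08 in RIP3, but adjusted p = 0.227 with an estimated correlation, and 5.89e-13 in IKK2, but adjusted p = 0.173 with an estimated correlation. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1440 genes were called in RIP3, 691 higher and 749 lower, and 702 in IKK2, 321 higher and 381 lower. The counts were 888 without WT replicate 2, 932 without RIP3 replicate 1 and 829 without RIP3 replicate 2 for RIP3, and 456 without WT replicate 2 for IKK2.

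RIP3 and IKK2 were compared directly, since a change against T2 in one and not in the other does not show that they differ. Gamma-delta T cells were 3.29-fold higher in RIP3 than in IKK2 (log2 1.72 ± 0.20, SE, n = 2; edgeR quasi-likelihood adjusted p = 3.73e-11) and pDCs 1.89-fold lower (log2 -0.92 ± 0.12, adjusted p = 1.79e-10 by the same test). B cells were higher in RIP3 by 0.33 ± 0.06 and NK or ILC1 cells by 0.58 ± 0.13, while cluster 6 lay at -0.55 ± 0.11. The NK or ILC1 clusters went opposite ways, though single clusters were not tested: cluster 9 made up 6.43% and 6.26% of the cells in RIP3 against 2.68% and 2.51% in IKK2, and cluster 15 1.92% and 1.62% against 3.13% and 2.51%. With cluster 6 joined to the NK or ILC1 cells their log2 ratio was -0.07, and -0.08 at a clustering resolution of 0.5. At that resolution an NK or ILC1 cluster of 1938 cells had Trdc, Klra5 and Cd160 among its top genes, as cluster 6 did. Both values thus rest on a like joining. The macrophage shares were not called different (log2 0.38 ± 0.30). Of 18 classes 6 were called, 3 higher and 3 lower, of which classical monocytes were not called without RIP3 replicate 1 or RIP3 replicate 2. T cells of RIP3 had lower cytotoxic genes than those of IKK2: 15 of 23 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 9.05e-35, but adjusted p = 0.21 with an estimated correlation). Nkg7, a protein of cytotoxic granules, was at -0.57 ± 0.05 and Klrg1 at -2.57 ± 0.31. Cluster 13, which is rich in these genes, held 8.48% and 8.09% of the T cells in RIP3 and 21.4% and 17.4% in IKK2. In pDCs 5 of 16 MHC class I genes were higher in RIP3 and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 1.34e-05, but adjusted p = 0.262 with an estimated correlation). H2-Q7 was up by 0.77. In Kupffer cells Marco was lower in RIP3 by -1.30 ± 0.12, and hepatocyte transcripts were lower, 4 of 11 with 0 up, 8 and 1 adjusted over the list alone (camera adjusted p = 5.47e-09, but adjusted p = 0.262 with an estimated correlation). Alb was at -1.43 ± 0.22. In all 534 genes were called, 239 higher and 295 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In cycling cells 0 of 4359 genes were called, with 299 at an unadjusted p under 0.05.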

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

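The tests of sex, mouse of origin and depth for the macrophages, of sex for the gamma-delta T cells and for the genes of RIP3, and of the chromosome segment were chosen only after the result was seen; the other tests were written before. The test of pDCs was written before its own value was seen, but it rests on Y-positive cells alone, a set chosen after seeing the data.

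Monocyte-derived macrophages made up 55.8% of the T2 cells and at most 1.74% of the cells of any other library. The T2 and RIP3 pools held cells of both sexes, and WT and IKK2 of only 1, but among Y-positive cells alone the T2 share was still 48.9 times the WT share (edgeR's quasi-likelihood test), which argues against mixed sex as the cause. If 1 mouse of the pool had carried the macrophages they would be of 1 sex, yet the lowest share among the cells of either sex in a T2 library was 49.8%, so at least a pair of mice carried them. The UMIs of T2 cells were also thinned to the lowest median of the other libraries. The highest UMI limit of those libraries was applied and the classes were kept. Macrophages then made up 67.1% and 64.5% of the T2 cells left. The limit kept 91.2% and 90.8% of the macrophages but only 59.1% and 60.5% of the other cells, which raises the macrophage share. The test therefore cannot decide on depth or the UMI limit. With 500 UMIs as the limit in every library, the T2 share was 54.8 times the WT share. Genotype is the biological difference that the design names, in hepatocytes and, for RIP3, in every cell, and a batch of sorting or loading that goes with the group, or the use of 1 pool per group, stays open and cannot be told apart from it.

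Gamma-delta T cells were a larger share in RIP3 than in IKK2, with a log2 ratio of 1.72, and pDCs a smaller one, at -0.92; both were flagged because the effects of both groups against T2 differed by edgeR's test of the difference. Among Y-positive cells alone the log2 ratios were 1.74 and -0.94, which argues against the mixed sex of the RIP3 pool. Differences of strain, batch or cage between the pools were not tested and stay open beside an effect of the genotypes.

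Some genes set RIP3 apart from each of the other 3 groups, the same way in 3 or more classes. There were 8, against 7 for WT, 223 for T2 and 1 for IKK2: Gdpd3 (chromosome 7, 126766334 to 126775649), Sh3bgrl3 (chromosome 4, 134127406 to 134128789) and its neighbour Cd52 (134082448 to 134095082) were higher in 10, 8 and 5 classes, and Ckb (chromosome 12), Samd9l (chromosome 6), Gm47283 (chromosome Y) and the processed pseudogenes Gm10036 and Gm10093, whose counts are uncertain, were lower. A chromosome segment carried along with the Ripk3 allele would place them near Ripk3 (chromosome 14, 55784995 to 55788865), but 0 of 8 lay within 20 Mb, with 0.154 expected. Among Y-positive cells alone all 8 genes kept their direction, with a median log2 ratio, signed by that direction, of 2.94 against WT and 3.22 against IKK2, which argues against the sex of the RIP3 cells. Their median share of free RNA was 2%, which argues against RNA from other cells in the droplets. Strain background elsewhere in the genome was not tested and could still account for genes such as Gdpd3, at 67 UMIs in WT, 281 in T2, 1260 in RIP3 and 70 in IKK2.

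Other shares were flagged by the same test of the difference between RIP3 and IKK2: B cells at a log2 ratio of 0.33, NK or ILC1 cells at 0.58, cluster 6 at -0.55 and classical monocytes at -0.64, the last with an adjusted p by edgeR's quasi-likelihood test of 0.00248 that became 0.0907 without RIP3 replicate 1 and 0.051 without RIP3 replicate 2. The number of genes changed between RIP3 and IKK2, 534, was flagged in the same way.

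Xist, which cells of females transcribe, was flagged as a signal outside the main measurement. It stood at 326.5 and 359.3 CPM (UMIs) in T2 and at 612.2 and 566.7 in RIP3, against at most 0.1 in WT and 0 in IKK2. Of the cells with Xist or Y-linked transcripts 53.19% and 56.22% were Xist-positive in T2, and 71.41% and 67.01% in RIP3.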

How the results depend on the processing

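The alternatives that use Y-positive cells, leave macrophages out of the total, use Scrublet's automatic threshold or join cluster 6 to NK or ILC1 cells were chosen only after the results were seen. Comparisons are listed here in the order T2 with WT, RIP3 with T2, IKK2 with T2, RIP3 with WT, IKK2 with WT and RIP3 with IKK2. The depth of RIP3 and IKK2, and the few B cells of T2, limit which genes pass. With 1 library of a group left out, the lone library is assumed to vary like the other groups.

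The number of genes called fell to 2087, 1929, 2043, 453, 219 and 180 with DESeq2's Wald test, and to 1166, 61, 576, 52, 100 and 12 in Y-positive cells, a fit of fewer cells and 2 groups. Leaving out 1 library at a time gave 3042 to 5553, 2724 to 4628, 2905 to 4874, 829 to 1601 and 456 to 776 genes for the first 5 comparisons. Lists called with an estimated correlation numbered 7, 14, 11, 0, 0 and 0; fry called 22, 4 and 12 in the last 3 comparisons. Leaving out 1 library gave 39 to 56 lists for IKK2 with WT and 22 to 38 for RIP3 with IKK2. Classes called among Y-positive cells numbered 10, 9, 7, 5, 3 and 3, and with neutrophils and B cells left out 11 for IKK2 with T2 and 4 for IKK2 with WT. The class calls for RIP3 with WT ranged from 5 to 9 with 1 library left out. Except for fewer cells, genes or classes by construction, the cause was not tested.

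The macrophage share of RIP3 against WT, not called at 0.59, ranged from 0.27 to 0.86 with 1 library left out. It was called at 0.66 with no upper limit on genes and doublets kept, at 0.68 with all barcodes of 500 or more UMIs, at 0.82 with neutrophils and B cells left out, and at 0.60 with the automatic doublet threshold. The cause was not tested.

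Some values changed sign. Among Y-positive cells of T2 against WT the shares of cDC1 (-0.18), cluster 22 (-0.44), gamma-delta T cells (-0.30) and plasma cells (-0.25) did so, as did Lef1 (0.04) and Il7r (-0.26) in T cells. Of RIP3 against T2 the shares of cDC1 (0.13) and cycling cells (0.05) did, and of IKK2 against T2 those of cDC1 (0.16), gamma-delta T cells (0.42) and plasma cells (0.45), with Lef1 (-0.06). With macrophages left out of the total, Kupffer cells (-0.08) and gamma-delta T cells (-0.15) of RIP3 against T2 and Kupffer cells (-0.15) and pDCs (-0.16) of IKK2 against T2 lay below 0, by construction of the shares. At resolution 2 classical monocytes were at 0.12 in RIP3 and 0.67 in IKK2 against T2. A cluster of 584 cells closest to that class stayed unnamed there, so the class held only the other monocyte cluster, of 505 cells. The NK or ILC1 share of RIP3 against IKK2 was -0.08 at resolution 0.5 and -0.07 with cluster 6 joined. At resolution 0.5 the NK or ILC1 class held a cluster with top genes of cluster 6, so both values rest on a like joining. For the changes among Y-positive cells the cause was not tested.

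Mice were pooled per group by the labels, so libraries with the same replicate number in different groups share no animal. Such libraries did not deviate together (median correlations from -0.028 to 0.003). The 2 libraries of a group may hold the same pool. With the number as a replicate block 4565, 3897, 4142, 1333, 642 and 502 genes, 118, 101, 103, 54, 37 and 32 lists, and 18, 15, 16, 9, 7 and 6 classes were called.

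Of 472 gene values named by the rule, 3 lost their call with DESeq2's size factors, 19 with no filter on low counts, 14 with no upper limit on genes and doublets kept, 27 to 49 without 1 library, 4 of 456 with free RNA subtracted and 17 of 462 with UMIs thinned; 90 of 434 did with DESeq2's Wald test. Among Y-positive cells, fitted with 2 groups, 66 of 174 lost their call and 3 changed sign, the largest share of any alternative. The replicate block ended 12 calls, the fit of 2 groups 15 of 469, the automatic doublet threshold 12 and the stricter cell filter 3. With no filter, 517 genes were higher and 977 lower in RIP3 against WT. Of 88 list calls, 0 were lost with size factors, 1 with free RNA subtracted, 0 to 3 without 1 library, 18 with fry and 70 with an estimated correlation. Of 102 shares of classes other than the macrophages, TMM factors on the class counts ended 2 calls and made 1, a minimum of 500 UMIs ended 8 and made 1, and the stricter cell filter made 2. Y-positive cells ended 26 and changed the sign of 9, and neutrophils and B cells left out ended 11 of 90 and made 3. The minimum of 500 UMIs also moved the B cell log2 ratios to -3.40, 3.79 and 3.47 in the first 3 comparisons. Each library alone in place of a sum was not run, because few barcodes were shared within a group, although RIP3 shared 28 against 4.1 by chance, for which the cause was not tested.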

Other observations

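The fits within T cell clusters and the choice of the lists here were made only after the results were seen.

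T cells of cluster 8, which holds both Lef1-rich and activated cells, differed between groups in their summed counts. At a clustering resolution of 2 a T cell cluster of 610 cells was led by Dapl1 and Lef1, and another of 398 cells by Tnfrsf4 and Ikzf2. The values below can therefore also reflect the mix of such cells. In T2 11 of 14 naive and central memory genes fell against WT and 0 rose, 12 and 0 adjusted over the list alone, with the transcription factors Lef1 at -1.92 ± 0.24 and Tcf7 at -2.53 ± 0.39 (SE, n = 2; camera adjusted p = 2.05e-18, and adjusted p = 0.00753 with an estimated correlation). Of 8 residency genes 6 rose and 0 fell, 7 and 0 adjusted over the list alone, with Rgs1 up by 2.62 ± 0.20 and Cxcr6, a receptor of liver-resident T cells, by 1.73 ± 0.23 (camera adjusted p = 3.4e-15, and adjusted p = 0.00753 with an estimated correlation). In cluster 1 Cxcr6 was lower in T2 than in WT, at -0.93 ± 0.14. Of 8 regulatory T cell genes 5 rose and 0 fell, 7 and 0 adjusted over the list alone, with Tnfrsf4 up by 3.12 ± 0.30 and Tnfrsf18, which encodes GITR, by 1.90 ± 0.23 (camera adjusted p = 7.8e-10, and adjusted p = 0.0231 with an estimated correlation). Tnfrsf4 was also higher than in WT in RIP3, by 1.66 ± 0.34, and in IKK2, by 1.82 ± 0.34. Against T2, 11 of the naive genes rose in RIP3 with 0 down (camera adjusted p = 4.95e-15, and adjusted p = 0.0094 with an estimated correlation) and 10 in IKK2 with 0 down (camera adjusted p = 1.61e-17, and adjusted p = 0.00572 with an estimated correlation). In cluster 13, the Gzmk and Cd8a cells, 7 of 17 cytotoxicity genes fell in T2 against WT and 1 rose, 9 and 1 adjusted over the list alone, with the granzyme Gzma 12.5-fold lower (camera adjusted p = 1.29e-09, and adjusted p = 0.0158 with an estimated correlation). In RIP3 against IKK2 10 fell and 0 rose, 11 and 0 adjusted over the list alone, with Gzma 12-fold lower and Ccl5 at -0.90 ± 0.11 (camera adjusted p = 2.44e-23, and adjusted p = 0.00433 with an estimated correlation).

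Conventional dendritic cells of type 1 (cDC1), which present antigen to CD8 T cells, and gamma-delta T cells also changed in T2 against WT. In cDC1 4 of 5 genes of the residency list rose and 0 fell, the same adjusted over the list alone, with Itgae up by 2.25 ± 0.27 and Bhlhe40 by 4.24 ± 0.49 (camera adjusted p = 1.09e-16, and adjusted p = 0.0421 with an estimated correlation); Itgae is CD103, also a marker of this cell type. Macrophage transcripts rose in the same cDC1 cells, among them C1qb by 2.25 ± 0.39, Spp1 by 3.44 ± 0.69 and Apoe by 2.09 ± 0.32. Of 26 immediate early genes 11 rose and 1 fell there, 16 and 3 adjusted over the list alone, with Atf3 up by 3.69 ± 0.40 and the chaperone Hspa8 at -0.68 (camera adjusted p = 1.62e-09, but adjusted p = 0.0596 with an estimated correlation). In gamma-delta T cells 5 of 9 residency genes rose and 0 fell, the same adjusted over the list alone, with Rgs1 7.62-fold higher (camera adjusted p = 3.5e-07, but adjusted p = 0.0603 with an estimated correlation), and Nkg7 changed by -2.95 ± 0.30. Myeloid and antigen-presenting transcripts rose in these T cells too, with H2-Eb1 up by 1.33 ± 0.34, Ctss by 1.26 ± 0.37 and Cxcl2 by 3.27 ± 0.77.

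The immediate early and dissociation response list was lower in all 11 classes in RIP3 and in IKK2 against WT by camera, and in 0 of them with an estimated correlation. The Kupffer cell call was lost in RIP3 without WT replicate 1 (camera adjusted p = 0.227), and in IKK2 without WT replicate 1 (0.0935) or IKK2 replicate 1 (0.563). In T2 against WT the list was higher in 4 classes and lower in 1.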
